A study of Mus musculus with 10 samples.

How the data were processed

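RNA was measured in mouse digit tip blastemas, the masses of proliferating cells that form at the end of an amputated digit. Each of the 10 libraries pooled tissue dissected from 6 amputated central hindlimb digits, per the labels. The mice were wild type or carried ΔLARM1/2, a deletion of LARM1 and LARM2, enhancers that drive Lmx1b in the limb. Tissue was taken 12 or 14 days post amputation (dpa), at an age of 33 or 35 days, from animals of mixed CD1 and C57Bl/6 background. Each day had 2 wild type and 3 mutant libraries. Total RNA libraries were made with a stranded Illumina kit after column extraction, per the labels' protocols; the strand setting used in counting is not given in the sources used here.

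The deposited expected counts and TPM values are per gene and per library, and their column layout is that of RSEM, per the file headers. The submitters' processing notes name FastQC, STAR 2.7.8a, RSEM 1.3.0 and the mouse build GRCm39, with no role or order given. The expected counts deposited by the authors were not normalized, and 13.9% of them were not whole, because RSEM divides reads that fit several genes. Reads of near-identical genes, such as keratins, keratin-associated proteins, histones and ribosomal proteins, can therefore be split among family members, and values for single members of these families are uncertain. The deposited TPM values are scaled by gene length and to a fixed total per library. A table of TPM for 21729 protein-coding genes over all 10 libraries was also deposited by the authors, and its values equalled those of the single libraries within 0.006. All of its columns could be matched to a library.

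Groups were taken from the titles. The library titled mutant 14 dpa replicate 1 carries a genotype tag of wild type, while its title, its description and the series design make it mutant; it was treated as mutant, and the tag was tried as an alternative. The titles and descriptions number the pair of wild type 14 dpa libraries in opposite order, and the titles were used. Each file listed 55416 Ensembl gene identifiers. Names came from a GENCODE M21 table on GRCm38 for 52083 identifiers and from the deposited TPM table for 50 more; 3283 had no name, and 914 names differed between the 2 sources. No genome of build GRCm39 was used here, so no coordinates are given.

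Total expected counts ran from 69998104 to 101632364 per library. Replicates of a group differed far beyond counting noise, with a chi-square of 155.8 to 303.1 per degree of freedom, so no pair was treated as 1 library. No label gives a sequencing date or batch. Sex was read from Xist and Y-linked counts, with 500 Y-linked counts as the minimum for a male. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these libraries, which may be partly technical. Intervals and floors cover counting error only.

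Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were kept by filterByExpr (minimum count 10, minimum total 15), leaving 20216, and libraries were scaled with TMM factors. All 10 libraries of the 4 groups entered 1 quasi-likelihood fit with robust dispersion estimates and no covariate. The common dispersion was 0.0767, a biological coefficient of variation of 0.277. Contrasts were mutant minus wild type at 12 dpa, at 14 dpa and averaged over both days, the difference between the genotype contrasts of the days, and 14 minus 12 dpa within each genotype. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Every adjusted p of a gene given without another tool's name comes from this edgeR test. CPM values use the TMM-scaled library sizes and are given as mean ± SD. Fitted log2 fold changes use a prior count of 0.125. Where a group had no counts, the fold is a lower bound against a floor of 3 counts over the group; with 1 to 3 counts, a ratio with its 95% counting interval is given.

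Before the data were examined, the comparisons, the alternatives, the gene lists and the rule for named genes were fixed. The 46 lists were nail plate and hair keratins and their regulators, keratin-associated proteins, epidermal keratinocytes, volar skin and eccrine sweat gland, dorsoventral limb patterning, distal limb Hox genes, digit blastema fibroblasts, small leucine-rich proteoglycans, collagens, extracellular matrix glycoproteins and crosslinking, tendon and ligament, osteoblasts and osteocytes, osteoclasts, chondrocytes, endothelium, angiogenic factors and receptors, pericytes and smooth muscle, lymphatic endothelium, neutrophils, monocytes and macrophages, inflammatory cytokines, chemokines and mediators, T and NK cells, B and plasma cells, dendritic and Langerhans cells with MHC class II, mast cells, interferon response, complement, Schwann cells and nerve, skeletal muscle, adipocytes, erythroid cells, megakaryocytes and platelets, melanocytes, sebaceous gland and hair follicle bulge, cell proliferation, canonical Wnt, BMP, FGF and hedgehog pathways, hypoxia response, matrix metalloproteinases and inhibitors, immediate early genes, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, replication-dependent histones, and sex-linked expression. The last list served to read sex and was not tested. The other 45 were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera asks whether a list moved relative to all other genes. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. Adjusted p-values given for lists are camera's unless another test is named.

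Named genes were Lmx1b; per genotype contrast the 8 largest rises and 8 largest falls among genes past the threshold that are in the protein-coding table, have a mean of at least 1 CPM and separate every mutant from every wild type library of the same day; and from each list up to 4 members past the threshold with the smallest p, or 2 given as values where none passed. In the time contrasts 5 and 5 genes, and for the difference between days 5 genes, were allowed; where no gene passed, the 3 of smallest p are given as not passing. Genes outside this rule are said to be chosen after their values were seen. The result of 1 gene that the rule allows is not reported here.

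The procedure was tested on simulated counts drawn from the means and library sizes of the real libraries. With 19628 genes, the genotype contrast over both days recovered 17.9%, 68.7% and 100% of genes changed 1.5-fold, 2-fold and 4-fold. It made 8 false calls among 132. At 12 dpa the shares were 2.99%, 35.8% and 84.8%, and at 14 dpa 2.99%, 34.3% and 81.8%. For 14 minus 12 dpa in mutants (19613 genes) they were 11.9%, 55.2% and 92.4%, with 12 false calls among 118. For the difference between days they were 0%, 0% and 65.2%, with 4 false calls among 47. Camera found the endothelium list when it was lowered 1.5-fold in simulated data (adjusted p = 1.21e-33; 0.000557 with an estimated correlation).

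Alternatives were relative log expression and upper quartile factors, DESeq2 1.42.0, limma-voom with and without quality weights, limma-trend on log2 of the deposited TPM plus 1 or plus 0.1, no filter, a strict filter, protein-coding genes only, only the libraries of a comparison, each library left out in turn, the replicate number as a block, the tagged library placed in wild type, and sex as a covariate. After seeing the data, 3 were added. The first left out both doubted 14 dpa libraries, meaning the tagged mutant library and the male wild type library with Xist counts. Another used male libraries only, which leaves a lone wild type library on each day. The last removed the nail keratin and keratin-associated genes before normalization. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, with scipy 1.17.1 for intervals and matplotlib 3.10.9 for plots.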

Results

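RNA was sequenced from digit tip blastemas of wild type mice and of ΔLARM1/2 mutants, which lack limb enhancers of Lmx1b, a homeobox gene that specifies dorsal limb identity. The study's title concerns failed digit tip regeneration without Lmx1b and functions of the gene apart from dorsoventral polarity. The 4 groups were wild type and mutant at 12 dpa and at 14 dpa, with 2 wild type and 3 mutant libraries on each day. Total expected counts were 74640170 and 75739468 in the wild type and 81549925, 77198028 and 81784761 in the mutant libraries at 12 dpa. At 14 dpa they were 69998104 and 85838038 in the wild type and 90904337, 101632364 and 75924098 in the mutant libraries. Libraries detected 24665 to 25305 genes in mutants and 24903 and 25240 in wild type at 12 dpa, and 23773 to 24713 and 25248 and 25647 at 14 dpa. Mitochondrially encoded mRNA took 0.826% to 0.933% of counts in mutants and 0.817% and 0.865% in wild type at 12 dpa, and 0.607% to 0.678% and 0.704% and 0.837% at 14 dpa. Genes of the protein-coding table took 92.3% to 93.7% of counts in mutants and 89.8% and 91.0% in wild type at 12 dpa, and 90.9% to 91.8% and 81.5% and 87.7% at 14 dpa. At 14 dpa the genotypes overlapped in none of these 3 quantities, and at 12 dpa in the first 2. The first principal component held 50.4% of the variance and separated the genotypes, and the second held 10.1% and separated the days. Each group contained 1 female library, and the other 6 were male.

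Lmx1b (ENSMUSG00000038765) was lower in every mutant library than in every wild type library. At 12 dpa it stood at 2.68 and 2.94 CPM in wild type and at 0.0788, 0.336 and 0.168 CPM in mutants. At 14 dpa the wild type libraries had 2.14 and 1.69 CPM, and the mutants 0.234, 0.0696 and 0.0278 CPM. The log2 fold change was -3.86 (SE 0.67, adjusted p = 0.00693) at 12 dpa, -4.11 (SE 0.70, adjusted p = 0.00402) at 14 dpa and -3.98 (SE 0.49, adjusted p = 0.000406) over both days. The mutant library with the wild type tag was the one at 0.234 CPM, and without it Lmx1b stood at -5.19 at 14 dpa. Without mutant 12 dpa replicate 2 the value at 12 dpa was -4.48. Placing the tagged mutant 14 dpa library in wild type ended the call, with adjusted p = 0.137 at 12 dpa, 0.568 at 14 dpa and 0.0599 over both days. With male libraries only, a setting chosen after seeing the data, the adjusted p was 0.148 at 12 dpa and 0.0805 at 14 dpa.

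**Figure D1:**
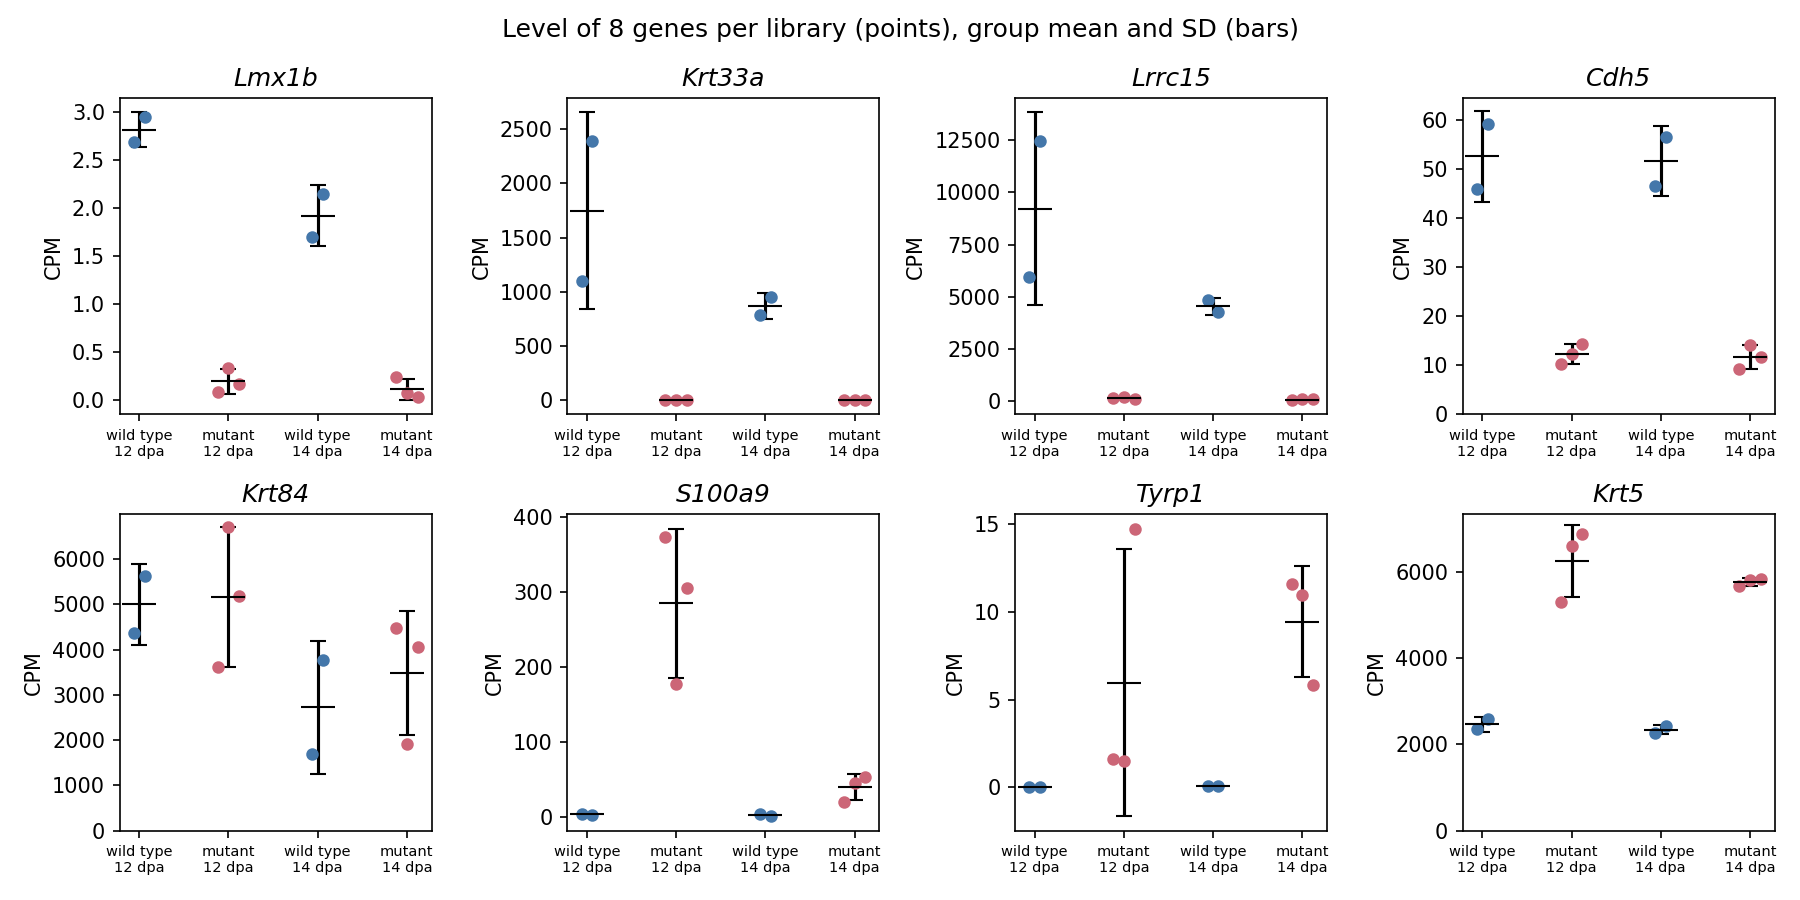
CPM of 8 genes in each library (points, linear axis with its own scale per gene), for wild type and mutant at 12 and 14 dpa; horizontal bars are group means and vertical bars SD (n = 2 wild type and 3 mutant libraries per day). Lmx1b, Krt33a, Lrrc15 and Cdh5 lie lower and S100a9, Tyrp1 and Krt5 higher in every mutant than in every wild type library, while Krt84, chosen after its values were seen, overlaps between genotypes.

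The comparison of mutants with wild type over both days asked which genes differ in the blastema when the Lmx1b enhancers are missing. Camera called 24 of the 45 gene lists, 7 higher and 17 lower in mutants, and 0 with an estimated correlation. The lower lists included nail keratins and regulators (20 of 29 members fell), endothelium (34 of 35), collagens (29 of 42) and blastema fibroblasts (20 of 27), and the higher ones keratinocytes (21 of 32 rose), inflammatory mediators (21 of 38) and melanocytes (8 of 12). The nail keratin Krt33a fell from 1310 ± 734 CPM (SD, n = 4) to 1.04 ± 1.2 CPM (SD, n = 6). Lrrc15, a membrane protein in the blastema fibroblast list, fell from 6880 ± 3810 to 92.6 ± 48.1 CPM. Cdh5, the vascular endothelial cadherin, fell from 52.2 ± 6.79 to 12 ± 2.06 CPM. Krt5, a keratin of basal keratinocytes, rose from 2400 ± 136 to 6010 ± 594 CPM, and the alarmin S100a9 from 3.27 ± 1.3 to 163 ± 149 CPM.

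By edgeR's quasi-likelihood test 8843 of 20216 genes changed over both days, 4354 higher and 4489 lower, and 6926 of them were in the protein-coding table. Changes exceeded 2-fold for 3708 genes. In 7529 genes, 37.2%, every mutant library lay on the same side of every wild type library of its day, where chance gives 2%. Placing the tagged mutant library in wild type left 0 genes past the threshold (5448 at an unadjusted p under 0.05), and with male libraries only, chosen after seeing the data, 3524 genes passed. The median log2 fold change over all genes was 0.02; on the TPM scale it was 0.14 with a pseudocount of 1 and 0.26 with 0.1, and the share of calls that were higher went from 49.2% to 71.8% and 71.9%. Changes on that scale include the raised median.

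Keratin-associated proteins had the lowest median of the 45 lists. All 45 tested keratin-associated proteins, which crosslink hard keratins, fell, also when adjusted over the list alone (median log2 fold change -7.26, camera adjusted p = 3.12e-62). Krtap16-3 was at least 33200-fold and Krtap19-2 at least 474-fold lower, both at 0 counts in mutants. Krtap11-1 fell by 6.75 on the log2 scale (SE 0.36, adjusted p = 1.97e-05). Of 29 nail keratins and regulators, 20 fell, 3 rose and 6 did not pass, and adjusted over the list alone 20 fell and 4 rose (median -2.56, camera adjusted p = 1.39e-19). Krt33a changed by -11.42 (SE 0.47, adjusted p = 4.95e-06) and Krt35 by -8.55 (SE 0.43, adjusted p = 1.97e-05). For both lists the adjusted p = 0.247 with an estimated correlation. Keratin-associated proteins took 2.63% of counts in wild type and 0.0992% in mutants, and nail keratins 6.14% and 3.96%. Gprc5d, a receptor of hard keratinizing cells, fell by 14.91 (SE 0.57, adjusted p = 4.64e-06); its value was -16.21 without mutant 12 dpa replicate 3 and -16.24 without mutant 14 dpa replicate 1.

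Among digit blastema fibroblast genes, 20 of 27 fell, 1 rose and 6 did not pass; adjusted over the list alone 21 fell and 1 rose (median -1.42, camera adjusted p = 4.65e-09). Lrrc15 changed by -6.23 (SE 0.31, adjusted p = 7.55e-06), the imprinted gene Mest by -3.01 (SE 0.30, adjusted p = 0.00026), and Msx1, a homeobox gene of the blastema, by -2.08 (SE 0.24, adjusted p = 0.000366). Of 42 collagens, 29 fell, 1 rose and 12 did not pass (adjusted over the list alone 30 and 1; median -1.22, camera adjusted p = 6.28e-13). Col4a1 of the basement membrane fell from 708 ± 102 to 175 ± 36.2 CPM, and Col10a1 of hypertrophic cartilage from 47.7 ± 30.8 to 0.928 ± 1.1 CPM. Of 42 matrix glycoproteins and crosslinking genes, 31 fell, 1 rose and 10 did not pass (34 and 1 adjusted over the list alone; median -1.20, camera adjusted p = 1.05e-11), among them the basement membrane gene Nid2 (-2.05, SE 0.18, adjusted p = 9.41e-05). Of 15 small leucine-rich proteoglycans, 9 fell and 6 did not pass (9 adjusted over the list alone; median -1.27, camera adjusted p = 3.57e-05). With an estimated correlation the adjusted p = 0.343 for fibroblasts and collagens and 0.455 for glycoproteins and proteoglycans.

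Skeletal genes fell in part. Of 20 chondrocyte genes, 12 fell, 2 rose and 6 did not pass (13 and 2 adjusted over the list alone; median -1.86, camera adjusted p = 4.9e-06, adjusted p = 0.311 with an estimated correlation). Col2a1, the main cartilage collagen, changed by -5.57 (SE 0.35, adjusted p = 2.01e-05) while Fgfr3 changed by 1.13 (SE 0.11, adjusted p = 0.000127). Of 28 osteoblast and osteocyte genes, 15 fell, 4 rose and 9 did not pass (16 and 5 adjusted over the list alone; median -1.73, camera adjusted p = 0.013, adjusted p = 0.587 with an estimated correlation). Runx2, the master regulator of osteoblasts, changed by -1.40 (SE 0.27, adjusted p = 0.00395). The list for tendon and ligament did not pass (7 fell, 2 rose and 3 did not pass of 12, the same counts adjusted over the list alone; median -1.08, camera adjusted p = 0.23), but did without mutant 14 dpa replicate 2 (0.0211). Osteoclast genes did not pass (2 fell, 1 rose, 16 not passing, the same adjusted over the list alone; median -0.12, camera adjusted p = 0.764). The list of matrix metalloproteinases and inhibitors had 12 lower, 2 higher and 13 not passing of 27 (13 and 3 adjusted over the list alone; median -0.45, camera adjusted p = 0.0489, adjusted p = 0.771 with an estimated correlation). That call was lost without wild type 12 dpa replicate 2 (0.0882), mutant 12 dpa replicate 1 (0.118) or 2 (0.143), wild type 14 dpa replicate 1 (0.0716) or mutant 14 dpa replicate 3 (0.0634), and under both other scaling factors (0.0503 and 0.0688).

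Lists of blood and lymph vessels, pericytes and angiogenic factors were lower in mutants. Of 35 endothelial genes, 34 fell and 1 rose, also adjusted over the list alone (median -1.78, camera adjusted p = 9.23e-26), and of 9 lymphatic endothelial genes, 7 fell and 2 did not pass (7 adjusted over the list alone; median -2.00, camera adjusted p = 8.33e-06). For both the adjusted p = 0.311 with an estimated correlation. Cdh5 changed by -2.12 (SE 0.14, adjusted p = 2.98e-05) and the lymphatic receptor Flt4 by -2.74 (SE 0.17, adjusted p = 1.97e-05). Pericyte and smooth muscle genes had 17 lower and 4 not passing of 21 (18 lower adjusted over the list alone; median -1.55, camera adjusted p = 2.66e-07), and angiogenic factors and receptors 26 lower, 2 higher and 12 not passing of 40 (26 and 2 adjusted over the list alone; median -1.02, camera adjusted p = 1.92e-09). With an estimated correlation the adjusted p = 0.343 for both. Mcam of pericytes changed by -1.80 (SE 0.16, adjusted p = 0.000101) and the semaphorin and VEGF coreceptor Nrp1 by -1.57 (SE 0.13, adjusted p = 7.1e-05). In the same libraries the keratinocyte list took 8.6% of counts in wild type and 14% in mutants.

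Among the epidermal lists, that of keratinocytes was higher in mutants. Of 32 keratinocyte genes, 21 rose, 0 fell and 11 did not pass (23 higher adjusted over the list alone; median 0.65, camera adjusted p = 1.12e-07, adjusted p = 0.343 with an estimated correlation). Krt5 changed by 1.32 (SE 0.13, adjusted p = 0.000123), its partner Krt14 by 1.05 (SE 0.15, adjusted p = 0.00072) and the adhesion molecule Epcam by 1.23 (SE 0.12, adjusted p = 0.000127). Volar skin and sweat gland genes did not pass (4 fell, 3 rose, 11 not passing of 18, the same adjusted over the list alone; median -0.26, camera adjusted p = 0.748). Sebaceous and bulge genes did not pass either (3 fell, 3 rose, 8 not passing, the same adjusted over the list alone; median 0.26, camera adjusted p = 0.608). Cytosolic ribosomal protein genes rose, with 71 of 87 higher, 1 lower and 15 not passing (75 and 1 adjusted over the list alone; median 0.56, camera adjusted p = 4.66e-14, adjusted p = 0.522 with an estimated correlation). Of 64 replication-dependent histones, 5 rose and 59 did not pass (3 adjusted over the list alone; median 0.49, camera adjusted p = 0.0027, adjusted p = 0.771 with an estimated correlation).

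Part of the inflammatory genes rose, and part of the macrophage genes fell. Of 38 inflammatory cytokines, chemokines and mediators, 21 rose, 0 fell and 17 did not pass (24 higher adjusted over the list alone; median 1.31, camera adjusted p = 2.75e-06, adjusted p = 0.343 with an estimated correlation). Lcn2, an iron-scavenging antimicrobial protein, changed by 5.39 (SE 0.61, adjusted p = 0.000457), the neutrophil attractant Cxcl2 by 5.85 (SE 0.85, adjusted p = 0.00127), and Tnf by 2.31 (SE 0.32, adjusted p = 0.00072). Lcn2 stood at 6.22 without wild type 12 dpa replicate 2, and Cxcl2 at 5.07 without mutant 12 dpa replicate 3. Of 25 genes in the list for neutrophils, 9 rose, 1 fell and 15 did not pass (9 and 1 adjusted over the list alone; median 1.56, camera adjusted p = 0.000163, adjusted p = 0.343 with an estimated correlation). This call was lost on the TPM scale (limma-trend and camera, 0.197 and 0.0943). S100a9 changed by 5.04 (SE 0.45, adjusted p = 0.000176) and S100a8 by 3.51 (SE 0.29, adjusted p = 9.41e-05). Of 28 genes of monocytes and macrophages, 11 fell, 1 rose and 16 did not pass (12 and 1 adjusted over the list alone; median -0.76, camera adjusted p = 0.0351, adjusted p = 0.771 with an estimated correlation), among them Adgre1 at -1.38 (SE 0.28, adjusted p = 0.00389). The macrophage call was lost without wild type 12 dpa replicate 1 (0.0525), mutant 12 dpa replicate 1 (0.0757) or 2 (0.132) or wild type 14 dpa replicate 1 (0.0597), and with upper quartile factors (0.0582) or the strict filter (0.0514). Without both doubted 14 dpa libraries, chosen after seeing the data, it was 0.0763.

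Of 32 interferon response genes, 16 fell and 16 did not pass (16 lower and 1 higher adjusted over the list alone; median -0.92, camera adjusted p = 0.0133, adjusted p = 0.771 with an estimated correlation). Without wild type 12 dpa replicate 1 the call was lost (0.154). The list for T and NK cells had 4 higher and 11 not passing of 15 (3 adjusted over the list alone; median 0.90, camera adjusted p = 0.0648). It passed without wild type 12 dpa replicate 1 (0.0274), mutant 12 dpa replicate 2 (0.0368) or 3 (0.0482), or mutant 14 dpa replicate 1 (0.0255). Genes of dendritic and Langerhans cells and MHC class II had 8 higher, 3 lower and 7 not passing (9 and 3 adjusted over the list alone; median 0.79, camera adjusted p = 0.154). They passed without mutant 12 dpa replicate 2 (0.0274). B and plasma cell genes had 1 higher, 2 lower and 3 not passing (the same adjusted over the list alone; median 0.17 with camera pointing down, adjusted p = 0.734). Mast cell genes had 1 higher, 1 lower and 8 not passing (0 and 1 adjusted over the list alone; median -0.28, camera adjusted p = 0.839). Complement genes had 1 higher, 3 lower and 13 not passing (the same adjusted over the list alone; median -0.28, camera adjusted p = 0.373).

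Most pigment genes rose. Of 12 melanocyte genes, 8 rose, 1 fell and 3 did not pass, also adjusted over the list alone (median 4.17, camera adjusted p = 0.0144, adjusted p = 0.771 with an estimated correlation). Tyrp1, an enzyme of melanin synthesis, went from 0.0283 ± 0.0264 to 7.7 ± 5.56 CPM (8.52, SE 1.16, adjusted p = 0.00103), Pmel changed by 4.80 (SE 0.80, adjusted p = 0.00226), and Tyr, with 0 wild type counts, was at least 273-fold higher. Without mutant 12 dpa replicate 3 Tyrp1 stood at 7.55 and Pmel at 3.90, and without wild type 12 dpa replicate 1 Tyrp1 stood at 9.75. Mitf, the transcription factor of melanocytes that other cells also express, fell from 35.5 ± 15.6 to 4.38 ± 1.49 CPM (-2.99, SE 0.26, adjusted p = 0.000133). The melanocyte list call was lost with limma-voom (0.0873), with quality weights (0.105), on the TPM scale (0.389 and 0.177), with the strict filter (0.0705) and without wild type 12 dpa replicate 1 (0.103) or 2 (0.0604).

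Of the signalling lists, the canonical Wnt list had 19 lower, 7 higher and 14 not passing of 40 (20 and 7 adjusted over the list alone; median -0.60, camera adjusted p = 0.00911, adjusted p = 0.587 with an estimated correlation). Lef1, a transcription factor of the pathway, fell from 18.9 ± 11.7 to 0.843 ± 0.236 CPM, and the nail gene Rspo4, a Wnt potentiator, changed by -2.85 (SE 0.32, adjusted p = 0.00027). The BMP list had 15 lower, 5 higher and 12 not passing of 32 (16 and 5 adjusted over the list alone; median -0.36, camera adjusted p = 0.00246, adjusted p = 0.346 with an estimated correlation), with Msx2 at -2.98 (SE 0.33, adjusted p = 0.000389). The FGF list (9 lower, 4 higher, 8 not passing, the same adjusted over the list alone; median -0.44, camera adjusted p = 0.28) and the hedgehog list (5 lower, 3 higher, 7 not passing, the same adjusted over the list alone; median -0.25, camera adjusted p = 0.214) did not pass. Limb patterning lists did not pass: dorsoventral genes had 4 lower, 2 higher and 5 not passing (the same adjusted over the list alone; median -0.45, camera adjusted p = 0.356), and distal Hox genes 9 lower, 4 higher and 5 not passing (the same adjusted over the list alone; median -0.60, camera adjusted p = 0.356). Hoxc13, a regulator of nail and hair keratins, changed by -1.10 (SE 0.21, adjusted p = 0.00354) and Hoxc10 by 1.15 (SE 0.20, adjusted p = 0.00191).

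Cell proliferation genes did not pass: 0 of 36 changed by either adjustment, over all genes or adjusted over the list alone (median -0.02 with camera pointing up, adjusted p = 0.81). The list of immediate early genes had 12 higher, 3 lower and 11 not passing of 26 (12 and 3 adjusted over the list alone; median 0.53, camera adjusted p = 0.0412, adjusted p = 0.771 with an estimated correlation). Its call was lost without mutant 12 dpa replicate 3 (0.137) or wild type 14 dpa replicate 2 (0.0916), on the TPM scale (0.0828 and 0.0746), with the strict filter (0.0875) and with protein-coding genes only (0.108). The hypoxia list had 7 higher, 8 lower and 14 not passing of 29 gene identifiers (7 and 10 adjusted over the list alone; median -0.11, camera adjusted p = 0.36), and mitochondrially encoded mRNAs 3 lower and 10 not passing (2 adjusted over the list alone; median -0.11, camera adjusted p = 0.401). Schwann cell genes (2 higher, 2 lower, 16 not passing, the same adjusted over the list alone; median -0.19, camera adjusted p = 0.627), skeletal muscle genes (3, 1 and 9; 3 and 1 adjusted over the list alone; median -0.03 with camera pointing up, adjusted p = 0.801) and adipocyte genes (3, 4 and 6; 3 and 4 adjusted over the list alone; median -0.66, camera adjusted p = 0.81) did not pass. Nor did erythroid genes (0 higher, 2 lower, 7 not passing, the same adjusted over the list alone; median -0.15, camera adjusted p = 0.442) or megakaryocyte and platelet genes (2, 2 and 4; 2 and 3 adjusted over the list alone; median -0.85, camera adjusted p = 0.289). In the latter Gp5, a platelet glycoprotein, changed by -6.66 (SE 0.29, adjusted p = 3.32e-06). Fry called 23 lists, of which camera also called 18.

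**Figure D2:**
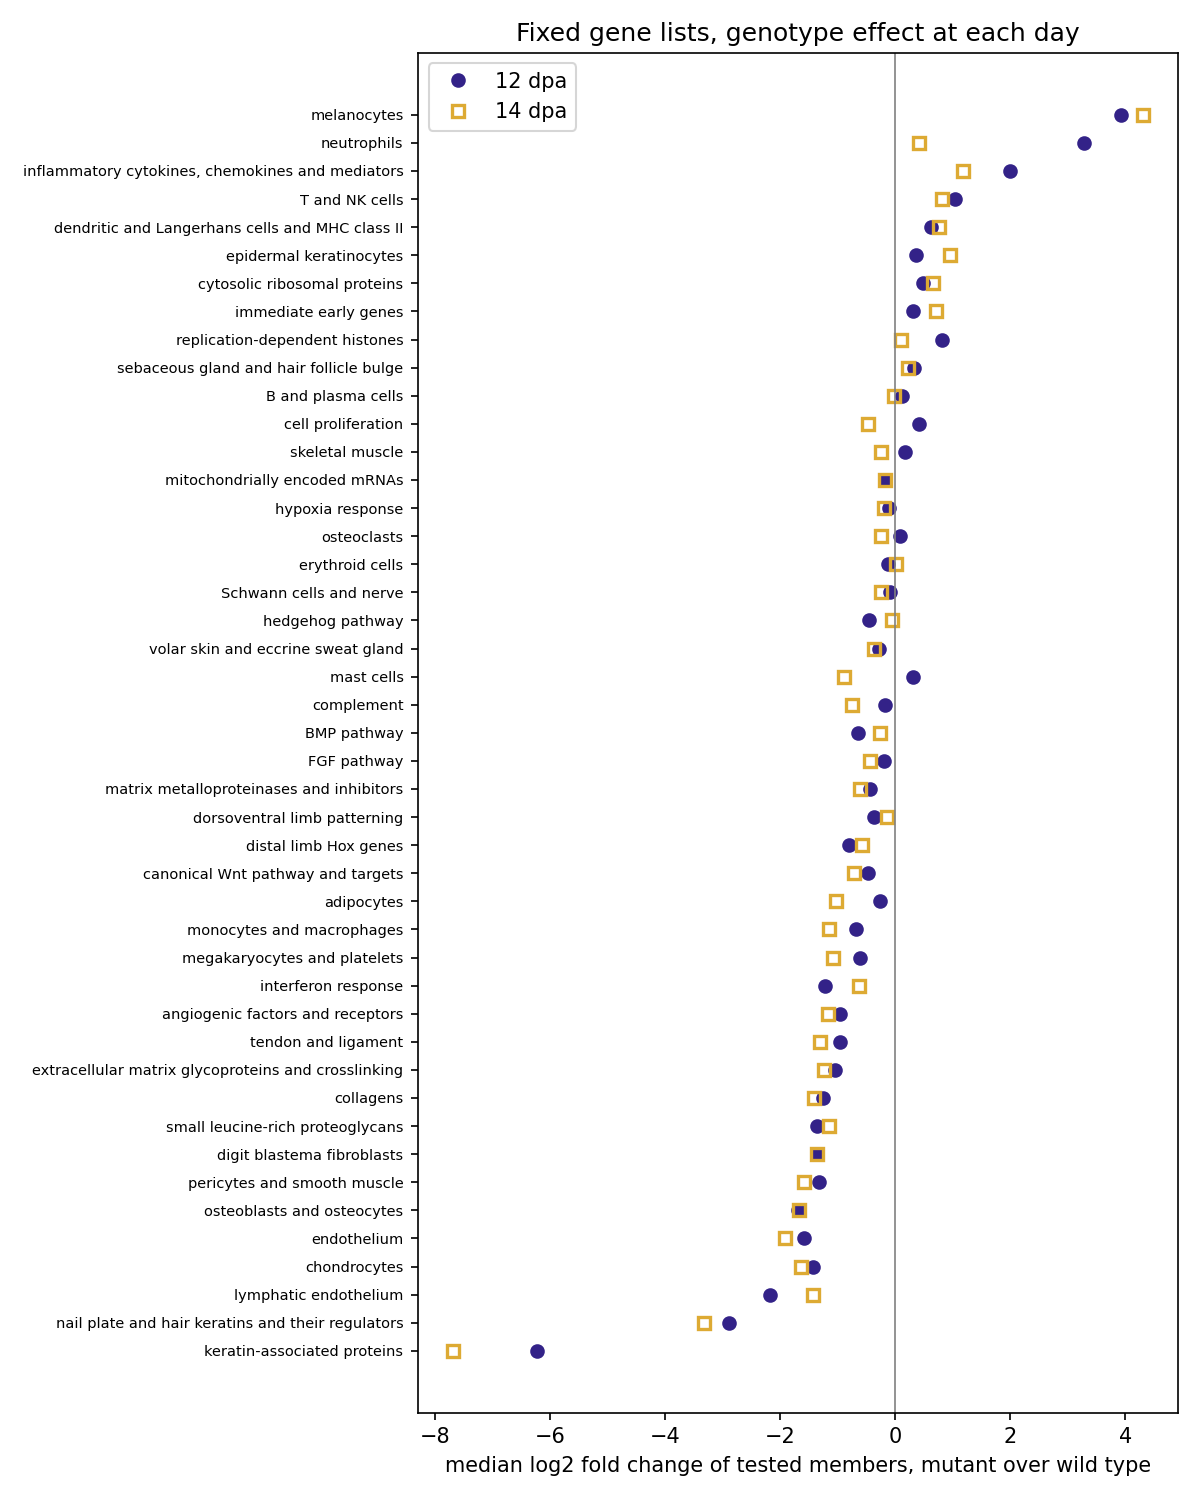
Median log2 fold change, mutant over wild type, of the tested members of each of the 45 gene lists at 12 dpa (filled circles) and 14 dpa (open squares). Keratin-associated proteins lie lowest on both days, at -6.22 and -7.69, and melanocyte genes highest, at 3.92 and 4.31.

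At 12 dpa camera called 22 lists, 7 higher and 15 lower in mutants, and 0 with an estimated correlation. The lower lists included nail keratins and regulators (17 of 29 fell) and endothelium (30 of 35), and the higher ones neutrophils (8 of 25 rose) and keratinocytes (7 of 32). Krt33a stood at 1750 ± 910 CPM in wild type (SD, n = 2) and 1.97 ± 1 CPM in mutants (SD, n = 3; -9.79, SE 0.61, adjusted p = 0.000156). Lrrc15 changed by -6.18 (SE 0.44, adjusted p = 0.000178), Cdh5 by -2.09 (SE 0.20, adjusted p = 0.000636) and Msx1 from 39.7 ± 1.26 to 8.1 ± 0.0738 CPM. S100a9 rose from 3.66 ± 1.49 to 286 ± 99.6 CPM (6.28, SE 0.67, adjusted p = 0.00144), and Lcn2 by 6.94 (SE 0.94, adjusted p = 0.00362). Without wild type 12 dpa replicate 2 Krt33a stood at -9.13, Lrrc15 at -5.55 and Lcn2 at 8.61, and without wild type 12 dpa replicate 1 Lcn2 stood at 6.19.

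The edgeR test called 3339 genes at 12 dpa, 1451 higher and 1888 lower, 2751 of them in the protein-coding table and 1949 changed over 2-fold. Genotypes were apart in 51.7% of all genes, where chance gives 20%. The count depended on single libraries: it was 769 without wild type replicate 2, 1509 without wild type replicate 1, 2166 without mutant replicate 1 and 2069 without mutant replicate 2, where a lone library left in an arm is assumed to vary like those of the other groups. It was 284 with male libraries only, chosen after seeing the data, and 0 with the tagged 14 dpa library in wild type (3957 at an unadjusted p under 0.05). The median log2 fold change over all genes was 0.03; on the TPM scales it was 0.16 and 0.29, and 71.8% and 74.5% of calls were higher against 43.5%.

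Of the 45 keratin-associated proteins tested, out of 58 in the list, 41 fell at 12 dpa and 4 did not pass, and 44 fell adjusted over the list alone (median -6.22, or -6.19 with genes at 0 counts at their bound; camera adjusted p = 7.28e-58). Krtap16-3 was at least 20900-fold lower. Gprc5d, at few mutant counts, had a ratio of mutant to wild type of 1.89e-05 (95% interval 2.28e-06 to 6.81e-05). Nail keratins and regulators had 17 lower, 2 higher and 10 not passing (19 and 3 adjusted over the list alone; median -2.88, camera adjusted p = 7.47e-20). With an estimated correlation the adjusted p = 0.189 for both lists. Endothelial genes had 30 lower, 1 higher and 4 not passing (32 and 1 adjusted over the list alone; median -1.59, camera adjusted p = 4.83e-23, adjusted p = 0.263 with an estimated correlation), lymphatic genes 5 lower and 4 not passing (7 adjusted over the list alone; median -2.17, camera adjusted p = 1.06e-06, adjusted p = 0.252 with an estimated correlation), and collagens 18 lower and 24 not passing (24 lower and 1 higher adjusted over the list alone; median -1.25, camera adjusted p = 6.88e-14, adjusted p = 0.321 with an estimated correlation). Flt4 changed by -3.25 (SE 0.24, adjusted p = 0.000178), Col4a1 by -2.03 (SE 0.22, adjusted p = 0.00105) and Col10a1 from 27.1 ± 6.91 to 0.0193 ± 0.0232 CPM. Blastema fibroblast genes had 11 lower, 1 higher and 15 not passing, the same adjusted over the list alone (median -1.36, camera adjusted p = 2.61e-08, adjusted p = 0.415 with an estimated correlation).

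Neutrophil-list genes at 12 dpa had 8 higher and 17 not passing (14 higher and 1 lower adjusted over the list alone; median 3.28, or 2.87 with bounds; camera adjusted p = 2.04e-07), and inflammatory genes 13 higher and 25 not passing (20 adjusted over the list alone; median 2.00, or 1.99 with bounds; camera adjusted p = 7.54e-08). For both the adjusted p = 0.263 with an estimated correlation. S100a8 changed by 4.49 (SE 0.42, adjusted p = 0.00082). Keratinocyte genes had 7 higher and 25 not passing (9 adjusted over the list alone; median 0.37, camera adjusted p = 0.00016, adjusted p = 0.538 with an estimated correlation), with Krt5 at 1.34 (SE 0.18, adjusted p = 0.00216). Cytosolic ribosomal protein genes had 23 higher and 64 not passing of 87 (36 adjusted over the list alone; median 0.49, camera adjusted p = 1.4e-10, adjusted p = 0.593 with an estimated correlation). Replication-dependent histones had 5 higher and 59 not passing (0 adjusted over the list alone; median 0.81, camera adjusted p = 2.75e-07, adjusted p = 0.632 with an estimated correlation). Cell proliferation genes had 1 higher and 35 not passing (0 adjusted over the list alone; median 0.41, camera adjusted p = 0.00209, adjusted p = 0.721 with an estimated correlation); the list for cell proliferation lost its call without wild type 12 dpa replicate 1 (0.126). The interferon response list had 8 lower and 24 not passing (13 adjusted over the list alone; median -1.22, camera adjusted p = 0.000379, adjusted p = 0.632 with an estimated correlation). Its call was also lost without that library (0.182). The list for melanocytes had 4 higher, 1 lower and 7 not passing (7 and 1 adjusted over the list alone; median 3.92, or 3.64 with bounds; camera adjusted p = 0.0233, adjusted p = 0.707 with an estimated correlation). That call was lost without wild type 12 dpa replicate 1 (0.155) or 2 (0.0547), with limma-voom (0.115, and 0.145 with weights), on the TPM scale (0.46 and 0.181), with the strict filter (0.0814) and with only the 12 dpa libraries (0.15). Fry called 15 lists at 12 dpa, of which camera also called 14.

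At 14 dpa camera called 20 lists, 5 higher and 15 lower in mutants, and 0 with an estimated correlation. The lower lists included nail keratins and regulators (19 of 29 fell) and endothelium (34 of 35), and the higher ones keratinocytes (18 of 32 rose) and ribosomal proteins (59 of 87). Krt33a stood at 868 ± 121 CPM in wild type (SD, n = 2) and 0.105 ± 0.0393 CPM in mutants (SD, n = 3; -13.04, SE 0.71, adjusted p = 9.71e-05). Lrrc15 changed by -6.28 (SE 0.44, adjusted p = 0.000177), Cdh5 by -2.15 (SE 0.20, adjusted p = 0.000554) and Col2a1 by -7.38 (SE 0.54, adjusted p = 0.000177). Epcam rose from 28.7 ± 0.958 to 109 ± 13.5 CPM (1.92, SE 0.17, adjusted p = 0.000442), and S100a9 from 2.88 ± 1.5 to 40.2 ± 17.3 CPM (3.79, SE 0.60, adjusted p = 0.0039; 4.41 without wild type 14 dpa replicate 2).

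The edgeR test called 6728 genes at 14 dpa, 3251 higher and 3477 lower, 5316 of them in the protein-coding table and 3375 changed over 2-fold. Genotypes were apart in 62.4% of all genes, where chance gives 20%. The count was 2548 without wild type replicate 1, 2633 without wild type replicate 2, and, in settings chosen after seeing the data, 1520 without both doubted libraries and 577 with male libraries only. It was 0 with the tagged library in wild type (1748 at an unadjusted p under 0.05). The median log2 fold change over all genes was -0.002, and 48.3% of calls were higher. With upper quartile factors the median was -0.11 and 36.4% were higher, and on the TPM scales the medians were 0.10 and 0.22 and 69.9% and 69.3% were higher.

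Of the 45 keratin-associated proteins tested, 44 fell at 14 dpa and 1 did not pass, also adjusted over the list alone (median -7.69, or -6.57 with bounds; camera adjusted p = 1.85e-54, adjusted p = 0.26 with an estimated correlation). Krtap16-3 was at least 12800-fold lower. Nail keratins and regulators had 19 lower, 2 higher and 8 not passing (19 and 3 adjusted over the list alone; median -3.32, camera adjusted p = 8.36e-16, adjusted p = 0.26 with an estimated correlation). Endothelial genes had 34 lower and 1 higher, also adjusted over the list alone (median -1.92, camera adjusted p = 1.98e-23), pericyte genes 12 lower and 9 not passing (15 adjusted over the list alone; median -1.59, camera adjusted p = 6.98e-07), and chondrocyte genes 9 lower, 2 higher and 9 not passing (12 and 3 adjusted over the list alone; median -1.64, camera adjusted p = 0.000191). With an estimated correlation the adjusted p = 0.441 for each. Collagens had 26 lower and 16 not passing (26 adjusted over the list alone; median -1.41, camera adjusted p = 7.06e-10) and blastema fibroblast genes 15 lower, 1 higher and 11 not passing (17 and 1 adjusted over the list alone; median -1.36, camera adjusted p = 3.69e-08). With an estimated correlation the adjusted p = 0.458 for both. Msx2 changed by -3.32 (SE 0.47, adjusted p = 0.00274), Lef1 by -4.72 (SE 0.63, adjusted p = 0.00222) and Mcam by -2.01 (SE 0.23, adjusted p = 0.00109). Lef1 stood at 32.9 and 9.67 CPM in the wild type libraries, and its change was -3.64 without wild type 14 dpa replicate 2 and -5.34 without replicate 1.

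Keratinocyte genes at 14 dpa had 18 higher and 14 not passing (21 adjusted over the list alone; median 0.96, camera adjusted p = 9.8e-10, adjusted p = 0.441 with an estimated correlation). Ribosomal protein genes had 59 higher and 28 not passing (73 adjusted over the list alone; median 0.66, camera adjusted p = 5.42e-15, adjusted p = 0.574 with an estimated correlation). Inflammatory genes had 13 higher and 25 not passing (18 higher and 1 lower adjusted over the list alone). Their median was 1.19 (camera adjusted p = 0.000383, or 0.506 with an estimated correlation). On the TPM scale with a pseudocount of 1 the call was lost (0.124). The list of immediate early genes had 10 higher, 3 lower and 13 not passing (14 and 3 adjusted over the list alone; median 0.72, camera adjusted p = 0.00314, adjusted p = 0.676 with an estimated correlation). That call was lost with the tagged library in wild type (0.501). The list for neutrophils did not pass (6 higher, 3 lower, 16 not passing, the same adjusted over the list alone; median 0.42, camera adjusted p = 0.123). It passed without wild type 14 dpa replicate 2 (0.0101) or mutant 14 dpa replicate 1 (0.0291) or, outside the contrast but in the same fit, mutant 12 dpa replicate 1 (0.0415) or 3 (0.00648), with the strict filter (0.000462) and with only the 14 dpa libraries (0.007). The list for melanocytes had 6 higher, 1 lower and 5 not passing (8 and 1 adjusted over the list alone; median 4.31, or 4.05 with bounds; camera adjusted p = 0.0231, adjusted p = 0.773 with an estimated correlation). Its call was lost with limma-voom (0.109, and 0.117 with weights), on the TPM scale (0.496 and 0.216), with the strict filter (0.0979) and with male libraries only (0.0599). Genes of cell proliferation had 2 lower and 34 not passing (0 adjusted over the list alone; median -0.47, camera adjusted p = 0.0358, adjusted p = 0.829 with an estimated correlation). That call was lost without wild type 14 dpa replicate 2 (0.561) or mutant 14 dpa replicate 1 (0.133) or 2 (0.174), with limma-voom and quality weights (0.103) and with sex as a covariate (0.0564). Fry called 18 lists at 14 dpa, of which camera also called 15.

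Of the genes called on each day, 2645 were called on both with the same direction, 1101 higher and 1544 lower. Of the 3339 genes called at 12 dpa, 3265 (97.8%) had the same direction at 14 dpa. Across the 20216 genes, which are not independent replicates, the log2 fold changes of the days had a Pearson correlation of 0.737. Both days share 1 fit, so their calls are dependent.

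The difference between the genotype contrasts at 14 and 12 dpa asked whether the mutant differed more on one day. Genes of cell proliferation had lower values at 14 relative to 12 dpa (median difference in log2 fold change -0.92, camera adjusted p = 1.73e-15), as did keratin-associated proteins (-1.57, camera adjusted p = 9.53e-13) and neutrophil-list genes (-2.49, camera adjusted p = 3.11e-07). Both sizes rest in part on fitted values of genes with 0 counts in a group. With such genes at their bounds the median genotype effects at 12 and 14 dpa were -6.19 and -6.57 for keratin-associated proteins and 2.87 and 0.42 for the neutrophil list. Genes of epidermal keratinocytes had higher values (0.38, camera adjusted p = 5.25e-06). For all of these the adjusted p = 0.956 with an estimated correlation, 0 members passed over all genes, and adjusted over the list alone 6 neutrophil-list genes were lower, 1 keratinocyte gene was higher and 0 passed in the others. The keratin-associated call was lost on the log2(TPM + 1) scale (0.427), the proliferation call with male libraries only (0.225), and keratinocyte genes turned lower with the tagged library in wild type (0.404). By the edgeR test 0 genes passed, with 1763 at an unadjusted p under 0.05; DESeq2 called 48, limma-voom 0 and limma-trend on log2(TPM + 1) 1. The smallest p-values belonged to Gm45062 (-4.38, SE 0.53, adjusted p = 0.208), Cxcl14, a chemokine of epidermis (1.37, SE 0.20, adjusted p = 0.544), and Gm6565 (adjusted p = 0.544), for which no size is given because wild type had 0 counts at 14 dpa. Without wild type 14 dpa replicate 2 the count was 3, and without mutant 12 dpa replicate 3 or wild type 14 dpa replicate 1 it was 1. Camera called 13 lists, 5 higher and 8 lower, and fry 0; the camera count was 8 without wild type 12 dpa replicate 1 or wild type 14 dpa replicate 1.

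From 12 to 14 dpa in mutants, the alarmin S100a8 fell from 201 ± 58.6 CPM (SD, n = 3) to 27.3 ± 6.22 CPM (SD, n = 3; -2.88, SE 0.33, adjusted p = 0.0426), and Slpi, a secreted protease inhibitor, from 27.1 ± 3.22 to 5.44 ± 0.881 CPM (-2.31, SE 0.26, adjusted p = 0.0426). Siah1a, a ubiquitin ligase, rose from 42.6 ± 3.89 to 75.8 ± 4.21 CPM (0.83, SE 0.10, adjusted p = 0.0426), and Csn1s1 fell from 5.02 ± 2.58 to 0.2 ± 0.135 CPM (-4.60, SE 0.58, adjusted p = 0.0479). The other 3 genes called lie outside the naming rule and were chosen after their values were seen. Col10a1 rose from 0.0193 ± 0.0232 to 1.84 ± 0.738 CPM (6.44, SE 0.71, adjusted p = 0.0426), Gm45062 fell from 7.32 ± 0.697 to 0.99 ± 0.327 CPM (-2.88, SE 0.34, adjusted p = 0.0426), and the unnamed gene ENSMUSG00000119873 rose from 0.00431 ± 0.00746 to 11.5 ± 6.51 CPM (adjusted p = 0.0153). Cell proliferation genes had lower values as a list (median -1.04, camera adjusted p = 3.06e-27), with 0 of 36 passing over all genes and 34 lower adjusted over the list alone. Keratin-associated proteins did likewise (median -2.46, or -2.35 with bounds; camera adjusted p = 2.94e-31), with 29 lower adjusted over the list alone. Ribosomal protein genes had higher values (median 0.44, camera adjusted p = 6.39e-25), with 57 higher adjusted over the list alone. The list of mitochondrially encoded mRNAs had lower values (median -0.49, camera adjusted p = 0.000571), with 7 lower and 3 higher adjusted over the list alone. In the last 3 lists 0 members passed over all genes. For each of these lists the adjusted p = 0.675 with an estimated correlation.

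The edgeR test called 7 genes between days in mutants, 3 higher and 4 lower, with 3803 at an unadjusted p under 0.05; limma-voom called 5 and DESeq2 1505. Groups were apart in 24.3% of all genes, where chance gives 10%. The count was 1 without wild type 12 dpa replicate 1 or 2 or mutant 14 dpa replicate 3, 3 without mutant 14 dpa replicate 2, and 23, 24 and 16 without mutant 12 dpa replicates 1, 2 and 3. S100a8, Slpi, Col10a1 and Gm45062 lost their calls without wild type 12 dpa replicate 1 (0.0843) or 2 (0.0844). S100a8 and Slpi also lost theirs without mutant 14 dpa replicates 1 (0.0979 and 0.081), 2 (0.116 and 0.102) or 3 (0.189 for both), and S100a8 without mutant 12 dpa replicate 3 (0.0635). Siah1a and Csn1s1 lost theirs without any single library other than mutant 12 dpa replicate 2, with adjusted p from 0.0504 to 0.189. Col10a1 lost its call also without mutant 12 dpa replicate 2 (0.0557) or 3 (0.0686) or mutant 14 dpa replicate 1 (0.0946) or 3 (0.189), and stood at 7.90 without mutant 12 dpa replicate 1 and 5.84 without replicate 3. It also lost its call with limma-voom (0.127, and 0.0986 with weights), on the log2(TPM + 1) scale (0.0944), with no filter (0.0599) and with only the mutant libraries (0.11). Gm45062 lost its call also without any mutant 14 dpa library (0.081, 0.0916 and 0.189). ENSMUSG00000119873 passed without each single library, at adjusted p of 0.0394 or less, but not with limma-voom (0.0968, and 0.0576 with weights). Camera called 15 lists, 5 higher and 10 lower, and 25 without mutant 14 dpa replicate 2; fry called 0. Also called were nail keratins (median -0.57, camera adjusted p = 1.3e-12, adjusted p = 0.659 with an estimated correlation; 12 lower adjusted over the list alone) and keratinocyte genes (0.42, camera adjusted p = 0.000136, adjusted p = 0.675 with an estimated correlation). The list for neutrophils was called as well (-1.27, or -1.24 with bounds; camera adjusted p = 0.000916, adjusted p = 0.675 with an estimated correlation), with 2 higher and 3 lower adjusted over the list alone. That call was lost without mutant 12 dpa replicate 3 (0.144) and on the TPM scale (0.746 and 0.706).

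The remaining 8 lists called between days in mutants had 0 members past the threshold over all genes. Values were lower for matrix metalloproteinases and inhibitors (median -0.71, camera adjusted p = 0.000662, adjusted p = 0.679 with an estimated correlation; 6 lower adjusted over the list alone), extracellular matrix glycoproteins and crosslinking (-0.35, 0.000802 and 0.881; 0 adjusted over the list alone), hypoxia response (-0.22, 0.00603 and 0.675; 6 lower and 1 higher), inflammatory cytokines, chemokines and mediators (-0.83, 0.00698 and 0.675; 4 lower) and osteoclasts (-0.69, 0.0144 and 0.842; 0). They were higher for immediate early genes (0.29, 0.00211 and 0.675; 1 higher), lymphatic endothelium (0.15, 0.0144 and 0.675; 4 higher) and erythroid cells (0.61, 0.0456 and 0.675; 0). Without mutant 12 dpa replicate 3 the calls of glycoproteins (0.0543), osteoclasts (0.854) and inflammatory genes (0.526) were lost, as they were without mutant 14 dpa replicate 1 (0.459, 0.0997 and 0.0683). Immediate early genes lost theirs without mutant 12 dpa replicate 1 (0.106) or mutant 14 dpa replicate 1 (0.0886), lymphatic endothelium without mutant 12 dpa replicate 2 (0.0681), and erythroid cells without wild type 12 dpa replicate 1 (0.102) or 2 (0.103), mutant 12 dpa replicate 1 (0.144) or 2 (0.0709), wild type 14 dpa replicate 1 (0.106) or mutant 14 dpa replicate 2 (0.163).

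From 12 to 14 dpa in wild type, keratin-associated proteins had lower values (median -1.07, camera adjusted p = 1.07e-08). Nail keratins did likewise (-0.77, camera adjusted p = 2.65e-06). Values were higher for cytosolic ribosomal proteins (0.26, camera adjusted p = 1.07e-08) and histones (0.55, camera adjusted p = 9.16e-09). For each the adjusted p = 0.988 with an estimated correlation, 0 members passed over all genes, and adjusted over the list alone 1 ribosomal protein gene was lower. Without wild type 12 dpa replicate 2 the calls of keratin-associated proteins (0.106), nail keratins (0.058) and ribosomal proteins (0.581) were lost. By the edgeR test 0 genes passed, with 1654 at an unadjusted p under 0.05; DESeq2 called 77, limma-voom 0, limma-trend on TPM 3 or 1, and edgeR on only the wild type libraries 8. The smallest p-values belonged to the unnamed gene ENSMUSG00000119873 (0.0409 ± 0.0578 CPM at 12 dpa and 18.1 ± 2.39 CPM at 14 dpa, SD, n = 2, edgeR adjusted p = 0.0934), Gm6565 (at least 109-fold lower, adjusted p = 0.3) and Cdv3 (-0.88, SE 0.13, adjusted p = 0.468). Groups were apart in 42.5% of genes, where chance gives 33.3%. The count was 4 without mutant 12 dpa replicate 3 or wild type 14 dpa replicate 2, 2 without mutant 12 dpa replicate 1 or mutant 14 dpa replicate 2, and 1 without wild type 14 dpa replicate 1. Camera called 12 lists, 5 higher and 7 lower, and 7 without wild type 12 dpa replicate 2; fry called 0.

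The other lists called between days in wild type each had 0 members past the threshold over all genes and an adjusted p = 0.988 with an estimated correlation. Values were lower for interferon response (median -0.56, camera adjusted p = 0.00955), osteoclasts (-0.46, 0.00955), hypoxia response (-0.10, 0.0232), extracellular matrix glycoproteins and crosslinking (-0.26, 0.0239) and mitochondrially encoded mRNAs (-0.27, 0.0239; 1 lower and 1 higher adjusted over the list alone). They were higher for mast cells (1.64, 0.00153), neutrophils (0.17, or 0.13 with bounds, 0.0182; 3 higher adjusted over the list alone) and complement (0.25, 0.0239). Adjusted over the list alone 0 members passed in the other 6 lists. Without wild type 12 dpa replicate 1 the interferon response turned higher (0.718), and the calls of mast cells (0.214), mitochondrial mRNAs (0.175) and complement (0.0719) were lost. Calls were lost without wild type 12 dpa replicate 2 for osteoclasts (0.134), hypoxia (0.398), glycoproteins (0.569), neutrophils (0.278) and complement (0.166), and without wild type 14 dpa replicate 1 for osteoclasts (0.175), hypoxia (0.0598), mitochondrial mRNAs (0.0836) and complement (0.149). They were lost without wild type 14 dpa replicate 2 for hypoxia (0.0806), glycoproteins (0.327), mitochondrial mRNAs (0.0591) and neutrophils (0.397), and for neutrophils without mutant 12 dpa replicate 1 (0.0705) or 3 (0.0961) or mutant 14 dpa replicate 1 (0.066) or 2 (0.0585).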

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

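The camera tests given here were chosen before the data were examined, and leaving out both doubted libraries and using male libraries only were chosen after. The lists below are given because a test of the difference itself found another genotype effect at 14 than at 12 dpa, relative to all other genes over the 10 libraries. Values are the median difference in log2 fold change, 14 minus 12 dpa, with camera's adjusted p over 45 lists. For each of the 13 lists the adjusted p = 0.956 with an estimated correlation, the smallest fry adjusted p was 0.889, and 0 members passed over all genes by edgeR. No technical or biological explanation was tested for these differences.

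Values were lower at 14 relative to 12 dpa for cell proliferation (-0.92, adjusted p = 1.73e-15), where the median genotype effect was 0.41 at 12 dpa and -0.47 at 14 dpa. They were lower for keratin-associated proteins (-1.57, adjusted p = 9.53e-13), where the day medians with genes at 0 counts at their bounds were -6.19 at 12 and -6.57 at 14 dpa, a call lost with the tagged library in wild type (0.257). Lower values were also found for replication-dependent histones (-0.73, adjusted p = 1.37e-07; 0.0681 with male libraries only) and neutrophils (-2.49, adjusted p = 3.11e-07; day medians with bounds 2.87 and 0.42), where 6 members were lower adjusted over the list alone.

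Values were higher at 14 relative to 12 dpa for epidermal keratinocytes (0.38, adjusted p = 5.25e-06) and immediate early genes (0.41, adjusted p = 0.000161), each with 1 member higher adjusted over the list alone. With the tagged library in wild type the first turned lower (0.404) and the second was lost (0.942). The list of cytosolic ribosomal proteins had higher values (0.17, adjusted p = 0.000423), lost without wild type 14 dpa replicate 2 (0.0863) and turned lower without wild type 12 dpa replicate 1 (0.968). Genes of the interferon response had higher values (0.70, adjusted p = 0.0196), lost without wild type 12 dpa replicate 1 (0.984) or wild type 14 dpa replicate 1 (0.055), and without mutant 12 dpa replicate 2 (0.0821) or mutant 14 dpa replicate 2 (0.414). The BMP pathway had higher values (0.13, adjusted p = 0.0357; 2 members higher adjusted over the list alone), lost without wild type 12 dpa replicate 2 (0.106), mutant 12 dpa replicate 1 (0.141), wild type 14 dpa replicate 1 (0.241) or mutant 14 dpa replicate 2 (0.252).

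The remaining lists had lower values near the threshold. The list of nail plate and hair keratins and their regulators (-0.46, adjusted p = 0.0327) lost its call without wild type 12 dpa replicate 1 (0.767), mutant 12 dpa replicate 2 (0.272), wild type 14 dpa replicate 2 (0.205) or mutant 14 dpa replicate 2 (0.135). For endothelium (-0.27, adjusted p = 0.0357) it was lost without wild type 12 dpa replicate 1 (0.52), mutant 12 dpa replicate 3 (0.443), wild type 14 dpa replicate 2 (0.0669) or 1 (0.0872), or mutant 14 dpa replicate 1 (0.845). For mast cells (-1.21, adjusted p = 0.0357) it was lost without wild type 12 dpa replicate 1 (0.568), mutant 12 dpa replicate 2 (0.0807) or 3 (0.323), wild type 14 dpa replicate 2 (0.105) or 1 (0.0605), or mutant 14 dpa replicate 1 (0.0892). For complement (-0.75, adjusted p = 0.0357) it was lost without wild type 12 dpa replicate 1 (0.0595) or 2 (0.156), mutant 12 dpa replicate 3 (0.443), wild type 14 dpa replicate 1 (0.185), or mutant 14 dpa replicate 1 (0.21) or 3 (0.0689).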

How the results depend on the processing

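Leaving out both doubted libraries, male libraries only and removing nail genes were chosen after seeing the data. A lone library left in an arm is assumed to vary like the others. Over both days, 4223 values of named genes under the alternatives had the direction and side of the threshold of the reported value, 350 no longer passed and 19 newly passed. At 12 dpa these counts were 3339, 604 and 11, and at 14 dpa 3740, 712 and 2. For lists they were 1112, 39 and 17 over both days, 1164, 14 and 35 at 12 dpa, 1136, 27 and 50 at 14 dpa, and 1042, 70 and 41 for the difference between days. Simulated recovery at 12 dpa (88 calls) may not hold for the 3339 real calls. Except where fewer libraries or genes entered, the cause of a change was not tested.

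With the tagged mutant library in wild type, 0 genes passed at 12 dpa, 0 at 14 dpa and 0 over both days, and 2 between days in mutants. Lmx1b was then -3.86, -4.71 and -4.28, no longer past the threshold, and 26 lists were called between days in wild type. For the difference between days these lists reversed: nail plate and hair keratins and their regulators (0.355), epidermal keratinocytes (0.404), digit blastema fibroblasts (0.000261), small leucine-rich proteoglycans (0.000529), extracellular matrix glycoproteins and crosslinking (3.29e-06), endothelium (0.000157), angiogenic factors and receptors (0.000392), pericytes and smooth muscle (0.00751), complement (0.942) and canonical Wnt pathway and targets (0.016). Between days in wild type the reversed lists were keratinocytes (0.00486), proteoglycans (0.0131), chondrocytes (0.0109), endothelium (0.000606) and pericytes (0.00237). At 14 dpa Il22ra2 reversed to -0.35.

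With male libraries only, 284, 577 and 3524 genes passed for genotype at 12 dpa, 14 dpa and both days. The count was 2 for the difference between days and 3 between days in wild type, with 6 lists there and 23 in mutants. Lmx1b was -3.54 at 12 dpa and -4.06 at 14 dpa, not past the threshold. For the difference between days collagens (0.0136), osteoblasts and osteocytes (0.0136) and interferon response (0.365) reversed, as did interferon response between days in wild type (0.8) and osteoblasts in mutants (0.0395). Without both doubted libraries, 1520 genes passed at 14 dpa and 1 between days in wild type, and extracellular matrix glycoproteins and crosslinking reversed for the difference between days (0.0231). Without nail genes 3238, 6416 and 8695 genes passed for genotype at 12 dpa, 14 dpa and both days.

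Genes called between days in mutants numbered 16 with upper quartile factors, 1505 with DESeq2, 46 with voom quality weights, 313 and 337 on log2(TPM + 1) and log2(TPM + 0.1), 45 with no filter, 19 with the strict filter, 26 with protein-coding genes only and 18 with sex as a covariate. Between days in wild type they numbered 77 with DESeq2, 3 and 1 on the TPM scales, 8 with only the wild type libraries and 2 with sex as a covariate. For the difference between days they numbered 48 with DESeq2, 1 on log2(TPM + 1) and 1 with no filter. Between days in wild type, inflammatory genes reversed on log2(TPM + 1) (0.0418) and neutrophils with the strict filter (0.795). Gata2 at 14 dpa reversed to 0.09 and 0.20 on the TPM scales. With an estimated correlation camera called 0 lists in each comparison, and fry 0 for the difference between days and between days in either genotype.

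The replicate numbers only number the libraries: deviations of same-numbered libraries had correlations from -0.0893 to 0.122 over 13 pairs, which is no pairing. With the replicate number as a block, 1927 genes passed at 12 dpa and 1 between days in mutants, and with the numbers of the descriptions 1921 and 0.

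Leaving out each library in turn gave 769 to 3947 genes at 12 dpa, 2548 to 6517 at 14 dpa, 6769 to 8797 over both days, 0 to 3 for the difference between days, 0 to 4 between days in wild type and 1 to 24 in mutants. Lists called ranged from 8 to 16 for the difference between days, 7 to 12 between days in wild type and 12 to 25 in mutants. The adjusted p of cytosolic ribosomal proteins for the difference between days ranged from 1.88e-12 to 0.968, that of interferon response between days in wild type from 3.82e-10 to 0.718, and that of osteoblasts and osteocytes in mutants from 0.00649 to 0.787. The first and second reversed without wild type 12 dpa replicate 1 (0.968 and 0.718), and the third without mutant 14 dpa replicate 2 (0.00649).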

Other observations

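The tests of explanations weighed here were chosen after the values they concern were seen, except the counts over other splits of the libraries. The test on vessel and matrix lists replaced a first version on 1 pair of lists, endothelium against macrophages (-0.95, exact permutation p = 0.01), and then one against 11 lists that left out skeletal cells, tendon and proteoglycans (-1.37, p = 0.01). The test of a single pigment source replaced one on 2 genes (a 1.67-fold range of the Tyrp1 to Pmel ratio), and that on S100a8, S100a9 and Lcn2 one of S100a9 against 5 genes (2.77 on the log2 scale, exact permutation p = 0.01). The outcomes of those earlier versions had also been seen.

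The genes of this paragraph were chosen after their values were seen. Among nail keratins, most of which fell, Krt84 did not pass (log2 fold change over both days 0.20, SE 0.31, adjusted p = 0.627 by edgeR). Krt6a, a keratin of wound and nail bed epithelium, was higher in 6 of 6 mutant libraries than in any wild type library (1.06, SE 0.19, adjusted p = 0.00224 by edgeR). Its partner Krt16 stood at 0.25 (SE 0.28, adjusted p = 0.484 by edgeR). The neutrophil granule genes Ngp and Ltf were highest in wild type 14 dpa replicate 2, at 2.97 and 1.54 CPM, while the inflammatory genes Il1b and Cxcl2 were highest in mutant 12 dpa replicate 3, at 17.8 and 23.1 CPM. The male wild type 14 dpa library had 1292 Xist counts, against 11 to 46 in the other males and 56782.70 to 133462.40 in females.

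Lists for endothelium, lymphatic endothelium, pericytes, blastema fibroblasts, collagens and matrix glycoproteins were lower in mutants, with a genotype effect of -1.58 on their mean log2 CPM. Nail keratin and keratin-associated genes took 8.77% of counts in wild type and 4.06% in mutants, which would raise other genes by 0.07 on the log2 scale and so goes against them as the cause. The 15 other lists of cells and matrix below the epidermis stood at -0.53 (exact two-sided permutation p = 0.07), a difference of -1.04 (p = 0.01, the smallest that 100 within-day splits can give), but the 6 lists were picked for being lower, and chondrocytes (-2.04, p = 0.01), osteoblasts and osteocytes (-1.54, p = 0.03) and small leucine-rich proteoglycans (-1.32, p = 0.01) fell as far as the weakest of them, so the difference decides nothing. Unadjusted and by the same permutation test, platelets (-0.94, p = 0.01) and adipocytes (-0.78, p = 0.02) were also lower, neutrophils (1.27, p = 0.03) and T and NK cells (0.67, p = 0.04) were higher, and skeletal muscle stood at -0.03 (p = 0.83). A smaller share of all tissue below the epidermis, fewer vascular and mesenchymal cells or a dissection that differed between genotypes may each lie behind the pattern; the first stays open because how far epidermis or immune cells within it express the other lists was not measured, and the other 2 were not tested.

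Pigment genes were higher in mutants, and Tyrp1 spanned 9.85-fold over the 6 mutant libraries. A variant in Tyr alone would leave the other members of the list unchanged, yet their median was 3.54 and 7 of 11 were called higher, and without mutant 12 dpa replicate 3 all 8 of the 8 members called higher were called again. For 1 source, such as melanocytes, as a candidate explanation, the members called higher varied around their shared profile with a median SD of 0.34 log2 CPM, against 1.49 for the profile itself. Dct, Pmel and Tyrp1 were the most abundant members in mutants (8.44 ± 5.38, 8.37 ± 5.92 and 7.7 ± 5.56 CPM, SD), 3 of the 12 tested reached a mean of 1 CPM in wild type, and 2, Kit and Sox10, are in another list. Mitf fell in the same libraries, and the mixed strain background and the dissection stay open as untested sources of a pigment difference.

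S100a8, S100a9 and Lcn2, picked from the neutrophil list for their large rises in mutants, changed by 4.70. The sum of the 18 other members with wild type levels no higher than S100a9 stood at 1.23 (exact two-sided permutation p = 0.09), a difference of 3.47 (p = 0.01, the smallest that 100 splits can give; 3.89 against all 22 others), which restates that choice and does not decide whether more neutrophils were the only source. The log2 ratio was -2.06 to -0.79 in the 4 wild type and 0.70 to 3.78 in the 6 mutant libraries. Asprv1, S100a9 and S100a8 were the most abundant members in mutants (2230 ± 1070, 163 ± 149 and 114 ± 102 CPM, SD), 8 of the 25 reached a mean of 1 CPM in wild type, and 3, Mmp8, Lcn2 and Hdc, are in another list. More neutrophils, expression in keratinocytes or another state of the neutrophils may each add to the rise; the first stays open because the level of these genes per neutrophil was not measured, and the others were not tested.

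For genotype over both days, 1 of 100 within-day splits, the real one, gave as many genes (8843 by edgeR, highest other 8). The others mix genotypes, so chance is unlikely but not excluded. For 12 against 14 dpa in mutants, the 10 splits are too few for a share under 0.05. The real split, 1 of the 10, gave 7 genes and the highest other 0.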
